A study of Mus musculus with 16 samples.

How the data were processed

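Gene expression was measured by RNA sequencing in liver of C57BL/6J mice, in 16 libraries of 4 groups. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a stranded mRNA kit (TruSeq). The submitters' processing notes name HISAT2 and StringTie without versions or roles, and the build as mm10 or GRCm38. The deposited counts are whole numbers per gene, with totals of 43.5 to 59.6 M per library, and which program made them is not given in the sources used here. The authors also deposited TPM values, which per the file headers are in TPM and whose sums lay between 998560 and 999351 per library. The deposited FPKM values were a constant multiple of TPM within each library. The titles of the 3 high-fat groups give 40% without saying of what, and no dose or feeding time is given in the labels.

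The tables list 16616 genes, each with a count of at least 1 in all 16 libraries, so a gene absent from 1 library is not analysed here. A median of 96.5 genes per library had a count of exactly 1, and a median of 13 of these had a TPM under 0.001, a sign that some counts were rounded up. Of the gene numbers, 16579 were found in the RefSeq gene table of GRCm38.p6, 16152 with the same symbol, and coordinates come from that table. The 4 gene entries whose symbol occurred more than once were kept apart by gene number. Reads shared by near-identical genes may have been split arbitrarily by the authors' counting, so values for Hamp and Hamp2, Orm1 and Orm2, the H2 genes, Cyp2j9 and Nat8 are uncertain in that respect, and so are those of the overlapping genes Gm2061 and Slc30a10.

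Groups were taken from the titles, and comparisons, tests, gene lists, naming rule and the other settings listed below were fixed before the data were examined. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr on the groups, which removed 666 genes and left 15950, and robust quasi-likelihood fits over all 16 libraries with a mean per group and no covariate. This left 12 residual degrees of freedom, and the common biological coefficient of variation was 23.7%. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 within a comparison. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values are scaled by the TMM library sizes.

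For gene lists, 34 lists of pathways and cell type markers were fixed, and 32 were tested. The pancreas list had 0 measured members, and the adipose tissue list had 1, under the minimum of 4. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison, and again with an estimated correlation and with fry. Counts of members use the adjustment over all genes, and counts adjusted over the list alone are given beside them. List scores are the mean over members of the z-score of log2 CPM with a prior count of 2, compared by exact two-sided permutation over the 70 arrangements of 4 against 4. The lists described in detail were picked after the list results had been seen.

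The rule for named genes took, per main comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM in a group, no overlap between groups and an established symbol, up to 4 members with the smallest p of each list described, and 9 genes in every comparison. Gm2061 and Gm15401 were named outside the rule, after their values were seen. Of the genes the rule took between the sweetened diets, 1 is not reported here, though counts and totals include it.

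The other settings tried were DESeq2 size factors and upper-quartile scaling, no filter on low counts and a mean count of at least 10, DESeq2 1.42.0, DESeq2 with an unadjusted p under 0.05 and a fold of at least 2, limma-voom with quality weights, a fit over the 2 groups alone, the replicate number as a block, a fold of at least 2, limma-trend on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1), and each library left out in turn. Another 3 settings were chosen after seeing the data: high-fat and D-allulose replicate 7 both left out, 36 mitochondrial and ribosomal RNA genes left out, and the slope of each library's log2 CPM on log2 transcript length as a covariate. Relative lengths for that slope came from the ratio of counts to FPKM, with FPKM of at least 0.1, for 15704 genes. Fold changes on the log2 scale of TPM or FPKM with a pseudocount understate changes of low genes.

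Replicates were checked for libraries deposited more than once. The lowest chi-square per gene between replicates was 23.9, so all 16 were counted as separate. The fits were tested on simulated counts for D-allulose against the high-fat diet (15849 genes, 200 of them changed). edgeR recovered 30%, 56%, 96% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, with 3.97% of its calls false, and DESeq2 48%, 76%, 98% and 100%, with 13.5% false. Between unchanged simulated groups edgeR called 0 genes. Each gene was drawn on its own with 1 spread for all groups, so these counts hold no differences shared by many genes of a library. The shares of false calls need not hold for the real libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.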

Results

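Liver RNA of C57BL/6J mice, a common inbred strain, was sequenced in 16 libraries that fall into 4 groups of 4: a normal diet, a high-fat diet, a high-fat diet with D-allulose, and a high-fat diet with erythritol. D-allulose is a rare sugar, an epimer of fructose, and erythritol is a sugar alcohol. Doses and feeding times are not given in the labels. The deposited counts summed to between 43.5 and 59.6 M per library over 16616 genes. The correlation of log2 counts over genes between replicates lay between 0.957 and 0.993. The total count, the share of the 10 most abundant genes and the share of the mitochondrial coding genes were compared in 12 exact two-sided permutation tests. The lowest p was 0.0571 (0.686 after Benjamini-Hochberg adjustment). D-allulose and erythritol were not set against the normal diet in these tests. TMM factors were 0.828 to 0.930 on the normal diet and 1.036 to 1.127 with erythritol, without overlap. They were 0.879 to 1.116 on the high-fat diet and 0.888 to 1.109 with D-allulose. Mitochondrial coding genes took 17.2% of the counts in high-fat replicate 5 and 11.8% in D-allulose replicate 7, against 5.91% to 9.02% in the other libraries. Nothing in the labels says that replicates came from separate mice, so p-values measure only the spread between these samples. Gene values below are normalised CPM, as mean ± SD with n = 4 per group, and log2 fold changes carry their standard error. Gene identifiers are NCBI gene numbers and positions are on GRCm38.

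On the high-fat diet, 20 of 25 genes of cholesterol synthesis and uptake fell (adjusted p = 0.0025 with an estimated correlation). Of the genes of the extracellular matrix and stellate cells 16 of 20 rose, of macrophages and Kupffer cells 10 of 21, and of the unfolded protein and integrated stress response 12 of 24 (adjusted p = 0.196, 0.229 and 0.196 with an estimated correlation). Sqle, squalene epoxidase, was at 1.01 ± 0.764 CPM on the high-fat diet and at 8.86 ± 2.68 on the normal diet (log2 fold change -3.13 ± 0.54, n = 4). Col1a1, a chain of type I collagen, was at 54.1 ± 35.6 against 4.07 ± 1.24 CPM (3.73 ± 0.62, n = 4). The gene with the largest rise under the rule for named genes was Themis, known for its role in T cell development (gene 210757, chromosome 10, 28668360 to 28883820), at 22.2 ± 9.94 against 0.583 ± 0.255 CPM, a 37.8-fold difference (5.24 ± 0.44, adjusted p = 2.54e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This comparison asks what the diet changed without a sweetener.

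Of the 25 measured members of the list for cholesterol synthesis and uptake, 20 fell on the high-fat diet (23 adjusted over the list alone). They included Idi1, an isomerase of the pathway (log2 fold change -2.92 ± 0.29), Fdps (-2.00 ± 0.18), Cyp51 (-1.78 ± 0.19) and Nsdhl (-1.53 ± 0.18). The list was called by camera with a preset correlation (adjusted p = 6.76e-34) and also with an estimated one (adjusted p = 0.0025 with an estimated correlation), which no other list was in any of the 4 comparisons. Of 26 measured genes of the urea cycle and amino acid catabolism, 13 fell (20 adjusted over the list alone). Got1, a transaminase, fell from 348 ± 131 to 56.0 ± 25.3 CPM (-2.64 ± 0.45). Gls2, a glutaminase (-1.63 ± 0.27), Sds, serine dehydratase (-1.85 ± 0.41), and Arg1, arginase (-1.24 ± 0.28), fell too. Camera called that list (adjusted p = 3.78e-14; adjusted p = 0.196 with an estimated correlation), and without high-fat replicate 5 the number that fell was 5.

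Of 20 measured genes of the extracellular matrix and stellate cells, 16 rose (18 adjusted over the list alone). They included Col3a1 (3.09 ± 0.52), Col1a2 (2.67 ± 0.49) and Col5a2 (2.38 ± 0.45). Camera gave adjusted p = 4.99e-13 (adjusted p = 0.196 with an estimated correlation). Of 21 macrophage and Kupffer cell genes, 10 rose (13 adjusted over the list alone). Gpnmb was higher by 5.09 ± 0.92, the integrin genes Itgax by 3.39 ± 0.57 and Itgam by 2.11 ± 0.40, and the chemokine receptor gene Ccr2 by 2.98 ± 0.48 on the log2 scale. Camera called this list too (adjusted p = 1.27e-07; adjusted p = 0.229 with an estimated correlation). High-fat replicate 7 stood apart in the matrix list, with a score of -1.09 against 0.60 to 0.83 in the other high-fat libraries and Col1a1 at 6.92 CPM against at least 46.5. In the macrophage list its score of -0.49 lay beside that of high-fat replicate 5 (-0.33), with 0.79 and 0.99 in the other 2, and Gpnmb was at 1.95 CPM in replicate 7 and 30.004 in replicate 5. Without high-fat replicate 7 18 matrix genes and 14 macrophage genes rose, and without high-fat replicate 5 the numbers were 10 and 9. The list of 15 sinusoidal endothelium markers was not called (median log2 fold change 0.01, camera adjusted p = 0.496).

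Of 24 genes of the unfolded protein and integrated stress response, 12 rose (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.89e-07; adjusted p = 0.196 with an estimated correlation). Examples are Trib3 (1.63 ± 0.22), Creld2 (1.46 ± 0.29), Manf (1.77 ± 0.40) and Hyou1, a chaperone of the endoplasmic reticulum (1.03 ± 0.21). Without high-fat replicate 7 the number that rose was 8, and without high-fat replicate 5 it was 7. Of 20 lipid droplet and fatty acid uptake genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00495; adjusted p = 0.196 with an estimated correlation). Lpl, lipoprotein lipase, rose from 21.2 ± 3.98 to 155 ± 56.1 CPM (2.87 ± 0.27), and Cd36, a fatty acid transporter (1.58 ± 0.26), Mogat1 (1.92 ± 0.40) and Fabp4 (1.56 ± 0.35) rose too. Among genes reported in every comparison, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (-2.10 ± 0.64), and so did G6pc, glucose-6-phosphatase (-1.18 ± 0.37). The values for Scd1 (-0.09 ± 0.37), Fasn (-0.14 ± 0.26), Pparg (0.45 ± 0.17), Cpt1a (-0.69 ± 0.23), Khk (-0.33 ± 0.18) and Fgf21 (0.22 ± 0.39) did not pass.

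In all, 1956 of 15950 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1381 higher and 575 lower on the high-fat diet, and camera called 22 of 32 lists, of which 1 stayed called with an estimated correlation. Other genes with large rises were Sdcbp2 (4.39 ± 0.75), Lcn2, lipocalin (3.69 ± 0.63), Ubd (3.64 ± 0.73) and Tnc, tenascin (3.56 ± 0.61). Large falls were those of Cyp17a1, a steroid hydroxylase (-3.48 ± 0.54), Hamp2, a hepcidin gene (-3.06 ± 0.42), and Fam222a (-2.76 ± 0.46). The share of calls that were higher was 70.6% here and 86.4%, 89.3% and 89.0% in limma-trend fits of log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1). Those fits called 560 higher and 88 lower, 875 and 105, and 1615 and 199. In those fits the median of all genes lay 0.12, 0.17 and 0.13 above 0 on the log2 scale. The count was 3789 without high-fat replicate 7, 1051, 832 and 1178 without high-fat replicates 3, 5 and 12, and 631, 761, 1201 and 1150 without normal-diet replicates 1, 4, 5 and 6. Cyp7a1 and G6pc lost their calls in 10 and 14 of 24 alternatives.

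With D-allulose in the high-fat diet, Nat8, an acetyltransferase gene, and Slc10a2, the sodium-dependent bile acid transporter of ileum and bile ducts, were lower than on the high-fat diet alone, and so were 8 of 24 genes of the unfolded protein and integrated stress response (adjusted p = 0.0804 with an estimated correlation). Nat8 (gene 68396, chromosome 6, 85830387 to 85836857) was at 1.13 ± 0.164 CPM against 7.18 ± 1.16 (log2 fold change -2.66 ± 0.18, n = 4, adjusted p = 2.39e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc10a2 (gene 20494, chromosome 8, 5083219 to 5105287) was at 2.34 ± 1.14 against 20.9 ± 3.08 CPM (-3.14 ± 0.34). Of 26 genes of the urea cycle and amino acid catabolism, 5 were higher and 1 lower (adjusted p = 0.613 with an estimated correlation), and 1 and 1 without D-allulose replicate 7. Among the higher ones was Sds, at 199 ± 112 against 33.3 ± 18.6 CPM (2.58 ± 0.42). The question is what D-allulose changed on top of the diet.

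Of the 24 measured genes of the unfolded protein and integrated stress response, 8 fell with D-allulose (15 adjusted over the list alone). Hspa5, the main chaperone of the endoplasmic reticulum, was at 264 ± 42.3 against 635 ± 199 CPM (-1.26 ± 0.26), and Dnajb9 (-1.06 ± 0.16), Hyou1 (-1.23 ± 0.21) and Creld2 (-1.67 ± 0.30) fell as well. Hspa5 lost its call in 8 of 24 alternatives, among them those without high-fat replicate 5 or D-allulose replicate 1, 2, 5 or 7, and Creld2 lost it in 5, Hyou1 in 3 and Dnajb9 in 1. Camera called the list as lower (adjusted p = 1.49e-14; adjusted p = 0.0804 with an estimated correlation). The list's mean z-score was -0.49 ± 0.18 with D-allulose and 0.78 ± 0.28 without (SD, n = 4). The exact two-sided permutation p = 0.0286 is the smallest that 4 against 4 allows, and it was 0.261 after adjustment over 128 such tests. The score was lower in each D-allulose library than in any high-fat library. Without high-fat replicate 7, high-fat replicate 5 or D-allulose replicate 7, the number of members that fell was 4, 4 and 3, and it was 1 with both number-7 libraries left out.

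**Figure D1:**
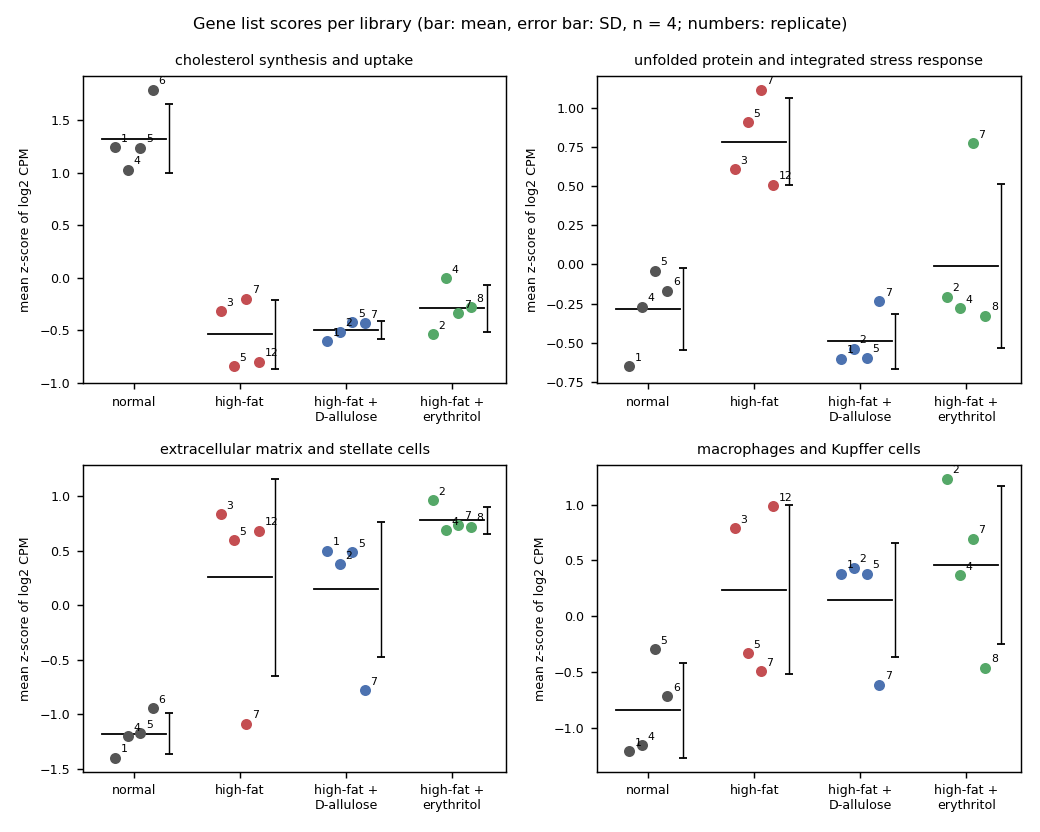
Mean z-score of log2 CPM over the members of 4 gene lists, 1 point per library with its replicate number, by group; horizontal bars are group means and error bars SD (n = 4). The unfolded protein response score averaged 0.78 on the high-fat diet and -0.49 with D-allulose, and replicate 7 of the high-fat and D-allulose groups lies below the rest of its group in the matrix list.

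Of the 26 genes of the urea cycle and amino acid catabolism, 5 rose and 1 fell with D-allulose (13 and 1 adjusted over the list alone; camera adjusted p = 7.23e-12; adjusted p = 0.613 with an estimated correlation). Sds, Got1 (1.83 ± 0.44), Gls2 (1.34 ± 0.27) and Cth, cystathionine gamma-lyase (1.51 ± 0.36), rose. Cth did not pass without any single library of the 2 groups (high-fat replicate 3, 5, 7 or 12 or D-allulose replicate 1, 2, 5 or 7), and Got1 did not without any of these but high-fat replicate 7. Over 24 alternatives Cth lost its call in 13, Got1 in 11, Gls2 in 5 and Sds in 2. Glul, which makes glutamine rather than breaking an amino acid down, fell from 1286 ± 137 to 731 ± 205 CPM (-0.81 ± 0.19), a call lost in 13 alternatives. D-allulose replicate 7 held the highest Sds value, 367 CPM, against 137 to 148 in the rest of its group. Without it 1 member rose and 1 fell, and without high-fat replicate 5 the number that rose was 2. Of 20 lipid droplet and fatty acid uptake genes, 4 fell (4 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.00517; adjusted p = 0.39 with an estimated correlation). These were Pparg, a nuclear receptor of lipid storage, from 22.6 ± 2.10 to 11.6 ± 2.79 CPM (-0.96 ± 0.17), Fitm1, which helps lipid droplets form (-2.60 ± 0.45), Mogat1 (-2.07 ± 0.40) and the droplet coat gene Plin4 (-1.97 ± 0.40), with calls lost in 7, 4, 5 and 5 of 24 alternatives. Of 16 gluconeogenesis and glycogen genes, 1 rose (5 adjusted over the list alone; camera adjusted p = 0.000182; adjusted p = 0.664 with an estimated correlation). That gene was Ppargc1a, a coactivator of fasting genes (1.23 ± 0.26), while Slc37a4 (0.88 ± 0.24), G6pc (1.23 ± 0.37) and Pck1 (0.96 ± 0.31) did not pass. Ppargc1a itself did not pass without high-fat replicate 5 or 12 or D-allulose replicate 2, 5 or 7.

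In all, 237 of 15950 genes passed, 85 higher and 152 lower with D-allulose, and camera called 13 of 32 lists, of which 0 stayed called with an estimated correlation. Among the largest changes were rises of Nup62cl (2.54 ± 0.56), Etnppl (2.42 ± 0.46), Cyp39a1, an oxysterol hydroxylase (1.84 ± 0.37), and Large2 (1.75 ± 0.41). There were falls of Serpina12, known as vaspin (-3.35 ± 0.64), Tpm2, a tropomyosin (-2.73 ± 0.30), and Themis (-2.64 ± 0.37). Scd1 (-0.67 ± 0.37), Fasn (-0.06 ± 0.26), Cd36 (-0.63 ± 0.26), Cyp7a1 (-1.04 ± 0.62), Cpt1a (0.22 ± 0.23), Khk (0.14 ± 0.18) and Fgf21 (-0.73 ± 0.39) did not pass. The share of calls that were higher was 35.9%, and 51.4% with upper-quartile scaling (113 higher, 107 lower) and 47.7% in limma-trend on log2(TPM + 1) (73 higher, 80 lower). The count was 37, 39, 66, 102 and 118 without D-allulose replicate 2, 5, 7, 1 and high-fat replicate 5, and 19 in a fit over the 2 groups alone. Of the genes named, Nat8 and Tpm2 kept their calls in all 24 alternatives, and Slc10a2 and Themis in 23. Calls were lost in 10 for Nup62cl and Large2, 8 for Cyp39a1 and 6 for Etnppl and Serpina12, and Nup62cl did not pass without high-fat replicate 3, 5 or 7 or D-allulose replicate 1, 2, 5 or 7.

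**Figure D2:**
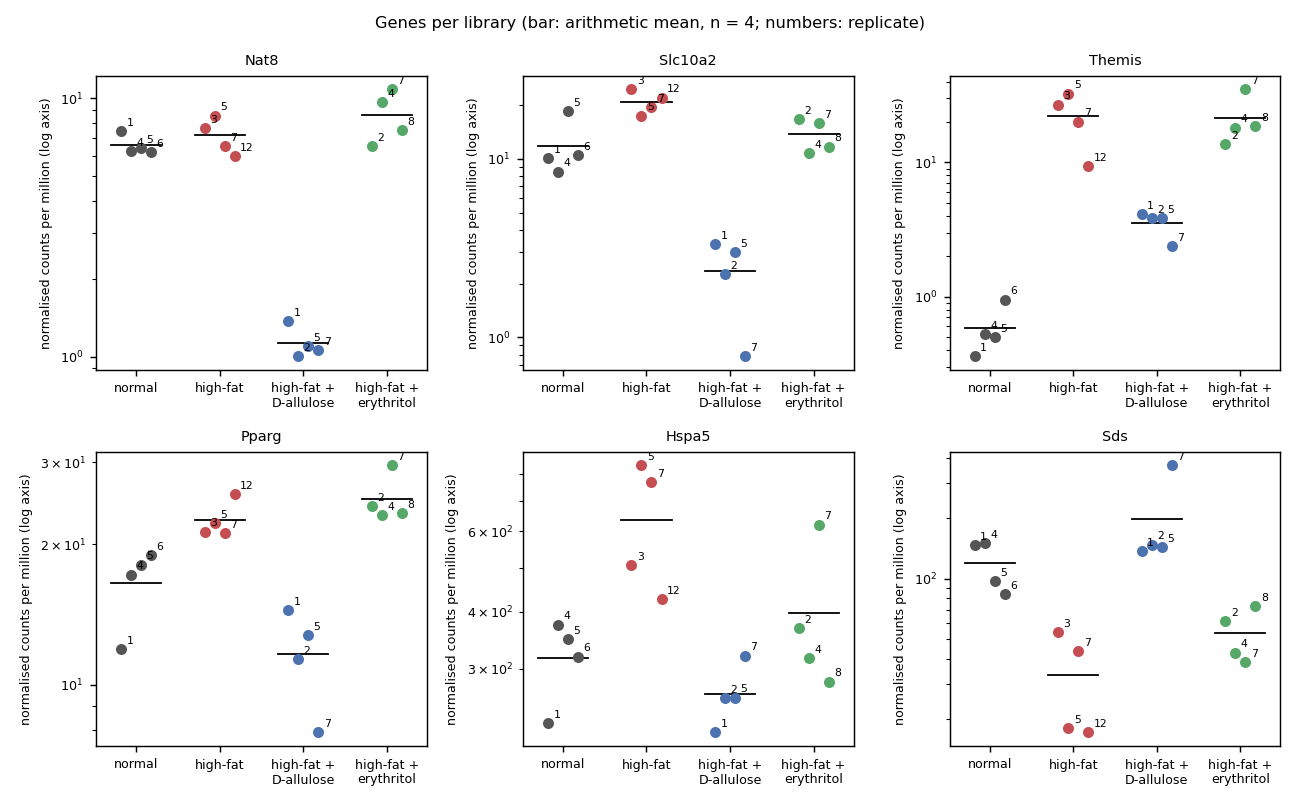
Normalised CPM of Nat8, Slc10a2, Themis, Pparg, Hspa5 and Sds on log axes, 1 point per library with its replicate number, by group; bars are arithmetic means (n = 4). Nat8 averaged 1.13 CPM with D-allulose against 7.18 on the high-fat diet and 8.64 with erythritol, and each D-allulose library lies below the libraries of the other groups.

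With erythritol in the high-fat diet, 3 of 15950 genes passed against the high-fat diet alone. Pde4b, a phosphodiesterase that breaks down cyclic AMP (gene 18578, chromosome 4, 102087332 to 102607275), rose from 10.01 ± 1.77 to 23.6 ± 3.24 CPM (log2 fold change 1.24 ± 0.19, n = 4, adjusted p = 0.0416 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The long noncoding RNA genes Gm2061 (-1.80 ± 0.26) and Gm15401 (-2.02 ± 0.31) fell. They went from 1.80 ± 0.449 to 0.516 ± 0.125 CPM and from 3.05 ± 0.913 to 0.748 ± 0.161 CPM, respectively. They lie outside the rule for named genes and were named after their values were seen. The annotated span of Gm2061 (chromosome 1, 185447116 to 185455568) overlaps that of Slc30a10 (185454848 to 185468762), so reads of the overlap cannot be assigned to 1 gene with certainty. The question is what erythritol changed on top of the diet.

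Camera called 8 of 32 lists between erythritol and the high-fat diet, of which 0 stayed called with an estimated correlation, and no list member passed the gene test. The list of the unfolded protein and integrated stress response was called as lower (adjusted p = 1.13e-12; adjusted p = 0.114 with an estimated correlation). In it 3 of 24 members were lower adjusted over the list alone, Creld2 (-1.21 ± 0.29), Dnajb9 (-0.59 ± 0.16) and Hyou1 (-0.71 ± 0.21), while Chac1 (-1.29 ± 0.47) did not pass that either. Erythritol replicate 7 went against this direction, with a score of 0.77 where the high-fat libraries lay between 0.51 and 1.12 and the other erythritol libraries between -0.33 and -0.21. The score had exact two-sided permutation p = 0.0857. The acute phase list was called as lower (adjusted p = 6e-08; adjusted p = 0.827 with an estimated correlation). It has the fibrinogen genes Fgb at -0.74 ± 0.29, Fga at -0.70 ± 0.29 and Fgg at -0.69 ± 0.29 and Itih4 at -0.73 ± 0.28. Erythritol replicate 7 went against this direction too, with an acute phase score of 1.10 where the high-fat libraries lay between 0.17 and 1.24. That score had exact two-sided permutation p = 0.171. The list of extracellular matrix and stellate cells was called as higher (adjusted p = 0.000367; adjusted p = 0.827 with an estimated correlation), with Pdgfrb at 0.69 ± 0.36, Mmp2 at 0.95 ± 0.52, Lum at 0.64 ± 0.46 and Des at 0.43 ± 0.23. Without high-fat replicate 7, the library low in matrix genes, its adjusted p was 0.689, in a range over all alternatives of 1.98e-12 to 0.877. In edgeR 0 members of these lists passed over all genes, and 0 of the acute phase and matrix lists passed adjusted over the list alone. At an unadjusted p under 0.05, 11, 5 and 0 members of the 3 lists differed, and DESeq2 and limma-voom called 0.

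None of the genes reported in every comparison passed with erythritol: Scd1 (-0.06 ± 0.37), Fasn (0.05 ± 0.26), Cd36 (-0.15 ± 0.26), Pparg (0.15 ± 0.17), Cyp7a1 (0.53 ± 0.62), Cpt1a (0.18 ± 0.23), Khk (-0.22 ± 0.18), G6pc (0.63 ± 0.36) and Fgf21 (-0.73 ± 0.39). At an unadjusted p under 0.05 lay 870 of 15950 genes. Chance alone would put a share of about 0.05 there, so the 870 cannot be read as that many changed genes. DESeq2 called 9 genes and limma-voom with quality weights 2. The 3 calls were 1 higher and 2 lower, against 0 and 1 in limma-trend on log2(TPM + 1) and log2(TPM + 0.1), where the median of all genes lay 0.12 and 0.17 above 0 on the log2 scale, and 2 and 1 on log2(FPKM + 1). The count fell to 0 without high-fat replicate 3, 5 or 12 or erythritol replicate 2, 4 or 8, and was 2 without high-fat or erythritol replicate 7. Without high-fat replicate 7, 1 of those 2 calls was of a gene not among the 3. A fit over the 2 groups alone also called 0 (501 at an unadjusted p under 0.05, fewer than chance alone would give).

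The direct comparison of the sweetened diets tests whether the livers under D-allulose and erythritol differed. Nat8 was 7.63-fold lower with D-allulose than with erythritol, 1.13 ± 0.164 against 8.64 ± 1.96 CPM (log2 fold change -2.93 ± 0.19, n = 4, adjusted p = 6.38e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc10a2 (-2.54 ± 0.34), Themis (-2.59 ± 0.37), Serpina12 (-3.37 ± 0.64) and Sdcbp2 (-3.54 ± 0.69) were also lower with D-allulose. Cib3, which codes for a calcium-binding protein, was at 0.490 ± 0.246 against 8.51 ± 2.46 CPM (-4.10 ± 0.83). Higher with D-allulose were Ntm (1.48 ± 0.28), Syt3, a synaptotagmin (1.21 ± 0.19), Cryl1 (1.06 ± 0.20), Cyp2j9 (1.06 ± 0.20) and Slc30a10, a manganese exporter (1.01 ± 0.19).

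Of 20 lipid droplet and fatty acid uptake genes, 2 were lower with D-allulose, Pparg at 11.6 ± 2.79 against 25.05 ± 3.06 CPM (-1.11 ± 0.17) and Fitm1 (-2.26 ± 0.44) (3 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0492; adjusted p = 0.674 with an estimated correlation). Fabp4 (-1.53 ± 0.35) and Mogat1 (-1.67 ± 0.40) did not pass. Without D-allulose replicate 7 the list's camera adjusted p was 0.0591 and 1 member was lower. It also lost its call without D-allulose replicate 5 (0.0934) and without erythritol replicate 4 (0.0582) or 7 (0.0978), and over all alternatives its adjusted p lay between 0.0141 and 0.674. Camera also called the lists of nuclear oxidative phosphorylation genes as higher (adjusted p = 1.09e-07), and of antigen presentation (adjusted p = 1.06e-05) and extracellular matrix and stellate cells (adjusted p = 0.000103) as lower with D-allulose, each at adjusted p = 0.674 with an estimated correlation. In edgeR 0 members of these passed over all genes and 0 adjusted over the list alone. Examples are Sdhd (0.47 ± 0.13) and Cycs (0.44 ± 0.17), Flt3 (-1.18 ± 0.42) and Ciita (-0.81 ± 0.33), and Tagln (-1.19 ± 0.49) and Loxl2 (-0.53 ± 0.28), none of which passed. At an unadjusted p under 0.05, 7 of 27, 5 of 11 and 1 of 20 members differed, DESeq2 called 1, 0 and 0 and limma-voom 1, 3 and 0. In D-allulose replicate 7 Col1a1 was at 9.74 CPM against 35.5 to 49.4 in the rest of its group, and without that library the matrix list had adjusted p = 0.0195, in a range over all alternatives of 4.28e-08 to 0.674. That library also stood apart in the scores of oxidative phosphorylation (1.56 against -0.36 to 0.35 in the rest of its group) and antigen presentation (-1.06 against -0.05 to 0.80). Without it these 2 lists had camera adjusted p = 0.000565 and 0.000914.

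In all, 55 genes differed between the sweetened diets, 11 higher and 44 lower with D-allulose, and camera called 16 of 32 lists, of which 0 stayed called with an estimated correlation. Scd1 (-0.62 ± 0.37), Fasn (-0.11 ± 0.26), Cd36 (-0.47 ± 0.26), Cyp7a1 (-1.57 ± 0.63), Cpt1a (0.05 ± 0.23), Khk (0.36 ± 0.18), G6pc (0.60 ± 0.36) and Fgf21 (0.01 ± 0.39) did not pass. The share of calls that were higher with D-allulose was 20%, and 8.3%, 0% and 8.8% in limma-trend on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1). Those fits called 3 higher and 33 lower, 0 and 22, and 5 and 52. On log2(TPM + 0.1) the median of all genes was -0.11. The count was 9, 11, 22 and 33 without D-allulose replicate 2, 7, 5 and 1 and 13, 11 and 34 without erythritol replicate 4, 7 and 8. Of the genes named, Nat8 kept its call in all 24 alternatives, and Themis and Slc10a2 in 23. Calls were lost in 13 for Sdcbp2, Ntm and Cyp2j9, 12 for Cib3 and Cryl1, 10 for Slc30a10, 9 for Serpina12 and Fitm1, 5 for Syt3 and 4 for Pparg. Sdcbp2 and Cib3 did not pass without any single library of the 2 groups, D-allulose replicate 1, 2, 5 or 7 or erythritol replicate 2, 4, 7 or 8.

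Against the normal diet, 824 genes differed with D-allulose (490 higher, 334 lower) and 3300 with erythritol (2315 higher, 985 lower). The cholesterol synthesis genes Idi1 and Fdps stayed lower than on the normal diet in both (log2 fold changes of -3.11 ± 0.30 and -2.19 ± 0.18 with D-allulose and of -2.81 ± 0.29 and -1.91 ± 0.17 with erythritol, n = 4). Themis rose by 2.60 ± 0.42 with D-allulose and 5.19 ± 0.44 with erythritol, and Nat8 fell with D-allulose (-2.54 ± 0.18) and did not pass with erythritol (0.39 ± 0.17). The share of higher calls with D-allulose was 59.5%, and 71.7% with upper-quartile scaling (712 higher, 281 lower), 73.3% (214 and 78) on log2(TPM + 1) and 78.3% (379 and 105) on log2(TPM + 0.1), where the median of all genes lay at 0.16 and 0.22. With erythritol it was 70.2%, and 95.9% (3759 higher, 159 lower), 96.2% (3839 and 150) and 93.4% (3780 and 266) on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1), with medians of all genes at 0.23, 0.31 and 0.15. It was 56.0% (2145 and 1687) with mitochondrial and ribosomal RNA genes left out. Without D-allulose replicate 7 the D-allulose count was 1737. It was 221, 188 and 172 without D-allulose replicates 1, 2 and 5, and 236, 316, 267 and 192 without normal-diet replicates 1, 4, 5 and 6. Without erythritol replicate 2 the erythritol count was 2116.

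Of the 237 genes called with D-allulose, 109 were also called between the high-fat and the normal diet, and 107 of these moved in opposite directions in the 2 comparisons. Higher on the high-fat diet and lower with D-allulose were 67, among them Themis, Tpm2, Sdcbp2, Mogat1, Hyou1 and Creld2. Another 40 were lower on the high-fat diet and higher with D-allulose, among them Sds, Got1 and Gls2. Independent lists of these sizes would share 13.2 and 3.06 genes in those directions. The high-fat libraries enter both comparisons with opposite sign, which pulls fold changes in opposite directions. Simulated unchanged groups called a mean of 0 and 0.05 genes in the 2 comparisons, so they give no overlap to set beside this one. The covariance of the fold changes was -0.120 against -0.0404 for simulated unchanged groups, a difference of -0.0800. The simulations used 1 spread per gene for all groups. The chi-square per gene between replicates reached 577 in the high-fat group and 219 in the others, so the simulated values may understate the pull of the shared libraries. With the high-fat libraries split 2 and 2 between the comparisons the mean covariance was -0.0484 and the median number of opposite genes 10.5, with means of 12.2 and 2.5 by direction where independent lists would share 8.27 and 1.20. The 6 splits fell into 2 sets. With high-fat replicate 7 set against the normal diet the correlation r lay between -0.44 and -0.35. With it set against D-allulose r was 0.0826, -0.00944 and -0.00976, and 46.2% to 48.4% of genes moved in opposite directions. For erythritol 1 gene, Pde4b, was called in both, and the covariance was 0.0150 against a simulated -0.0407, with a mean of 0.0840 in the splits (-0.0210 to 0.196). D-allulose and erythritol shared 1 called gene against the high-fat diet, again Pde4b (1.00 ± 0.19 with D-allulose), with a covariance of 0.0615 against a simulated 0.0405 and a mean of -0.00304 in the splits (-0.0364 to 0.0339).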

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

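All tests of explanations in this part, and the splits of the samples, had their expectations written after the result was seen, while the comparison of the sweetened diets was planned. Of 300 groups of 4 libraries examined for a library far from the rest, by the gap to its nearest neighbour over the range of the group, 19 held one, and chance gives about 1 in 20.

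High-fat replicate 7 and D-allulose replicate 7 stood below the rest of their groups in the score of extracellular matrix and stellate cells, at -1.09 and -0.78, where the next values were 0.60 and 0.37, and D-allulose replicate 7 also in that of macrophages and Kupffer cells, at -0.61. On the first principal component (55.7% of variance) high-fat replicate 7 lay at -33.9, beside the normal diet (-41.4 to -34.2), and D-allulose replicate 7 at -21.0, but the tables argue against normal-diet livers under a wrong label, since the lower of the pair's positions on the cholesterol synthesis list was 1.06, with 0 the mean of the normal diet and 1 that of erythritol. Less non-parenchymal tissue would lower all such markers alike. As a mean of the 2 libraries, the median log2 difference from the rest of the group was -0.14 for endothelium (quartiles -0.28 to -0.03). It was -1.50 for matrix genes (-2.19 to -1.13), -1.92 for cholangiocytes, -1.46 for antigen presentation and -0.86 for macrophages. The endothelium mean hides a difference between the libraries. In D-allulose replicate 7 the endothelium score was the lowest of its group (-0.51, against 0.02 to 1.37). In high-fat replicate 7 it was 0.001, within the range of the others (-1.25 to 0.54). A loss of all such cells therefore cannot be excluded for D-allulose replicate 7, nor a loss of those 4 kinds in either library. The scaling factors of these libraries differed from the rest by -0.29 on the log2 scale, less than the medians of those 4 lists. A difference between mice in the response to the diet was not tested and may remain as an explanation.

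Libraries also parted 2 and 2 within groups. The split of D-allulose replicates 1 and 7 with erythritol replicates 2 and 7 from the rest called 373 genes, several times the number between the sweetened diets, which points to a structure of the samples. The 337 genes lower on that side had a median transcript length 2.33 times that of all tested genes (1.03 to 1.22 in 95% of 10000 random lists), and the 36 higher genes 0.421 times, so a bias of the libraries with transcript length is a candidate explanation. Less endothelium in those pieces cannot be told apart, since the median of its markers lay at percentile 13.1 of random lists matched on length and expression. Slopes on length ran from -0.132 (high-fat replicate 5) to 0.103 (erythritol replicate 4). The normal diet parted too, with replicates 1 and 4 at -0.098 and -0.090 and replicates 5 and 6 at 0.020 and 0.025. With the slope as a covariate, 4200 of 15950 genes were called on the slope term, though the slope came from the same counts. No difference of slopes between groups was shown, with exact permutation p from 0.171 to 0.943 in 6 tests. The labels give no batch.

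D-allulose changes ran opposite to those of the high-fat diet in 107 of 109 genes called in both. The high-fat libraries shared by both comparisons pull fold changes in opposite directions, so D-allulose was also compared with the high-fat diet on the 3300 genes called between erythritol and the normal diet. Of these, 62.8% moved opposite to the difference from the normal diet, with a median signed difference of -0.09 on the log2 scale and an exact two-sided permutation p of 0.543, while erythritol moved opposite in 18.3% of the 824 genes called between D-allulose and the normal diet (median 0.28, exact p = 0.0571). A reversal by D-allulose and the shared libraries therefore cannot be told apart. On the 3300 genes the median for D-allulose was opposite in sign, but its exact permutation p of 0.543 left both open.

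Each comparison was set against all 35 splits of its 8 libraries, in fits over the 2 groups alone. The genes called outnumbered those of every other split between the high-fat and the normal diet (501, highest other split 0, 1 of 35 splits as large), D-allulose and the high-fat diet (19, highest other 0, 1 of 35), D-allulose and the normal diet (2110, highest other 208, 1 of 35) and erythritol and the normal diet (4711, highest other 15, 1 of 35). A share of 1 of 35 is the smallest the splits allow, and it was not adjusted over comparisons. It argues against chance without excluding it, and it covers these 2-group fits, not the calls made over all libraries. For erythritol against the high-fat diet edgeR called 0 genes in all 35 splits. In the real one 501 lay at an unadjusted p under 0.05, fewer than chance alone would give. Over all libraries DESeq2 called 9 and limma-voom 2. With all splits tied at 0, the number of calls cannot decide about chance there. Chance cannot be excluded for the sweetened diets (60, highest other 373, 2 of 35). For gene lists it cannot be excluded in any of the 4 comparisons: 22 lists with 22 in the highest other split and 2 of 35 as large for the high-fat diet, 12 with 23 and 18 of 35 for D-allulose, 9 with 21 and 34 of 35 for erythritol, and 15 with 23 and 21 of 35 between the sweetened diets.

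Between the sweetened diets 55 genes differed, by a test of the difference itself. In log2 fold change of D-allulose against erythritol, Ntm was at 1.48, Syt3 at 1.21, Cryl1 at 1.06, Cyp2j9 at 1.06 and Slc30a10 at 1.01. Lower with D-allulose were Cib3 at -4.10, Sdcbp2 at -3.54, Serpina12 at -3.37, Nat8 at -2.93, Themis at -2.59, Slc10a2 at -2.54, Fitm1 at -2.26 and Pparg at -1.11.

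Other values lay far from the rest of their group. Erythritol replicate 2 had the lowest total, 43.5 M counts, with 49.9 M next. In D-allulose replicate 7 mitochondrial coding genes took 11.8% of counts (7.57% next), the score of mitochondrially encoded transcripts was 1.62 (-0.29 next) and that of the urea cycle and amino acid catabolism 1.23 (0.06 next). The score of NRF2 and glutathione was 0.92 in high-fat replicate 12 (-0.08 next), that of the unfolded protein and integrated stress response 0.77 in erythritol replicate 7 (-0.21 next), that of the cell cycle 0.84 in erythritol replicate 2 (0.40 next) and that of immediate early genes -0.33 in erythritol replicate 4 (0.56 next). In CPM, Sds was at 367 (148 next) and Themis at 2.37 (3.84 next) in D-allulose replicate 7, Pparg at 29.6 (24.2 next) and Pde4b at 18.8 (24.9 next) in erythritol replicate 7. Khk was at 112 (200.4 next) and Nup62cl at 2.26 (0.633 next) in high-fat replicate 12, Cyp17a1 at 11.9 (2.92 next) in high-fat replicate 3 and Ntm at 1.47 (2.00 next) in normal-diet replicate 5.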

How the results depend on the processing

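The settings with both number-7 libraries left out, with mitochondrial and ribosomal RNA genes left out and with a length covariate were chosen after the result was seen, and the others were planned. No named gene called in the main fit or in an alternative had opposite directions in the 2, and no list called in both did. A list that changed direction and lost its call was counted as a lost call. Over all genes, 214 of 152941 values of called genes had the opposite sign under an alternative, 0 of them called there, and 115 of 40960 calls made by an alternative alone had the opposite sign in the main fit. Most were for erythritol against normal diet on log2(TPM + 0.1), log2(TPM + 1) and log2(FPKM + 1) (92, 91 and 26, and 29, 35 and 36). The covariance of D-allulose and erythritol changed sign, from 0.0615 to -0.00304 with the high-fat libraries split, and calls for D-allulose against high-fat diet went from 35.9% to 51.4% higher with upper-quartile scaling. Over all alternatives, values of named genes kept their side of the threshold 3185 times, lost the call 416 times and gained one 47 times. For gene lists these numbers were 1654, 171 and 91, and for list scores 119, 5 and 4. Among named genes, Themis and Hamp2 (high-fat against normal diet), Nat8 and Tpm2 (D-allulose against high-fat diet) and Nat8 (D-allulose against erythritol) kept their calls in all 24 alternatives. Counts below are of called genes, set against 1956 for high-fat against normal diet, 237 for D-allulose against high-fat diet, 3 for erythritol against high-fat diet, 55 for D-allulose against erythritol, 824 for D-allulose against normal diet and 3300 for erythritol against normal diet, and apart from the ranges for single libraries each differs by over 1.5 times. Upper-quartile scaling gave 32 for D-allulose against erythritol. DESeq2 gave 2946 for high-fat against normal diet, 860 for D-allulose and 9 for erythritol against high-fat diet, 363 between the sweetened diets and 2078 for D-allulose against normal diet. With an unadjusted p under 0.05 and a fold of at least 2 it gave 536 for D-allulose and 164 for erythritol against high-fat diet, 402 between the sweetened diets, and 1286 and 2102 for D-allulose and erythritol against normal diet. Limma-voom gave 2963 for high-fat against normal diet, 917 between the sweetened diets, and 4995 and 5583 for D-allulose and erythritol against normal diet. Fits over the 2 groups alone gave 501 for high-fat against normal diet, 19 for D-allulose and 0 for erythritol against high-fat diet, and 2110 for D-allulose against normal diet. A fold of at least 2 left 1044 for high-fat against normal diet, 124 for D-allulose against high-fat diet, and 491 and 1799 for D-allulose and erythritol against normal diet. On log2(TPM + 1) limma-trend gave 648 for high-fat against normal diet, 153 for D-allulose and 1 for erythritol against high-fat diet, 36 between the sweetened diets and 292 for D-allulose against normal diet, and on log2(TPM + 0.1) it gave 980, 147, 1, 22 and 484 in the same order. On log2(FPKM + 1) it gave 402 for D-allulose against normal diet. With both number-7 libraries left out the counts were 4129 for high-fat against normal diet, 71 for D-allulose against high-fat diet, 27 between the sweetened diets and 2844 for D-allulose against normal diet. With the length covariate they were 3481 for high-fat against normal diet, 644 for D-allulose and 0 for erythritol against high-fat diet, 152 between the sweetened diets and 1641 for D-allulose against normal diet. With each library left out in turn, counts ran from 631 to 3789 for high-fat against normal diet, from 37 to 256 for D-allulose and from 0 to 2 for erythritol against high-fat diet, from 9 to 46 between the sweetened diets, from 172 to 1737 for D-allulose against normal diet and from 2116 to 2816 for erythritol against normal diet. For erythritol against high-fat diet, the settings with 0 calls in edgeR had between 501 and 1595 genes at an unadjusted p under 0.05. Chance alone would give a share of about 0.05 of the genes tested. The replicate block gave 3 for high-fat against normal diet, 30 for D-allulose and 0 for erythritol against high-fat diet (1287 at an unadjusted p under 0.05), 6 between the sweetened diets and 2054 for erythritol against normal diet. Of 9 pairs of libraries with the same number, 4 had deviations from their group means correlated above 0.1 (r from -0.298 to 0.588), and 3 of 12 libraries correlated best with their own number. All 3 of these libraries are number 7, whose 3 pairs had r of 0.588, 0.285 and 0.321. Most other pairs lay under 0.1, so the numbers as a whole did not pair the samples. Something shared by the number-7 libraries cannot be excluded. Under the block 81 named-gene calls were lost, and for high-fat against normal diet Themis and Hamp2 alone of the named genes passed. The block adds a term per number and so leaves fewer residual degrees of freedom than the main fit. Normal-diet replicate 6, high-fat replicates 3 and 12 and erythritol replicate 8 hold numbers of no other library, so it fits them exactly. Lost calls under the block therefore cannot be told apart from this loss of precision. Of 32 gene lists, an estimated correlation left 1 of 22 called for high-fat against normal diet, 0 of 13 for D-allulose and 0 of 8 for erythritol against high-fat diet, and 0 of 16 between the sweetened diets. Fry called 1 for D-allulose, 0 for erythritol and 0 between the sweetened diets. For erythritol the block and leaving out both number-7 libraries each gave 13 lists, and single libraries left out gave 9 to 13. Genes moved opposite ways by the diet and the sweetener numbered 107 for D-allulose and 1 for erythritol, and 1 gene moved with both sweeteners. With the high-fat libraries split 2 and 2 the medians were 10.5, 0 and 0, and at an unadjusted p under 0.05 the numbers were 619, 101 and 374. The cause of these differences was not tested. At totals of 43.5 to 59.6 M counts, a gene at 1 CPM has 43.5 to 62.5 counts per library after TMM scaling, so depth limits genes under that level most.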

Other observations

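No explanation was tested in this part, and the lists described here were picked after the result was seen. On the high-fat diet, of 11 cholangiocyte genes 5 rose (10 adjusted over the list alone; camera adjusted p = 2.03e-05; adjusted p = 0.229 with an estimated correlation), including Krt23, a keratin (log2 fold change 2.72 ± 0.35, n = 4), Cftr, a chloride channel (3.07 ± 0.77), Spp1, osteopontin (2.12 ± 0.58), and Muc1 (1.79 ± 0.52). Cftr, Spp1 and Muc1 lost their calls in 10, 11 and 12 of 24 alternatives, among them the fit over the 2 groups alone. None of these 3 passed without normal-diet replicate 1, 5 or 6 or high-fat replicate 3 or 5, nor Spp1 and Muc1 without normal-diet replicate 4, nor Muc1 without high-fat replicate 12. Without high-fat replicate 7 the number of cholangiocyte genes was 10, and without high-fat replicate 5 it was 1. Of 11 antigen presentation genes 9 rose (10 adjusted over the list alone; camera adjusted p = 3e-09; adjusted p = 0.196 with an estimated correlation), among them Ciita, the activator of class II genes (1.77 ± 0.35), and the class II genes H2-Eb1 (2.06 ± 0.42), H2-Aa (2.01 ± 0.42) and H2-Ab1 (1.81 ± 0.38). Of 22 acute phase genes 8 rose (9 adjusted over the list alone; camera adjusted p = 1.19e-05; adjusted p = 0.256 with an estimated correlation), among them Il1rn (2.10 ± 0.37), Orm2 (2.76 ± 0.54) and Steap4 (1.42 ± 0.32). Of 15 hepatokine genes 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.00916; adjusted p = 0.196 with an estimated correlation). Gdf15 rose (2.62 ± 0.68), and Enho (-1.71 ± 0.33) and Hamp, hepcidin (-2.16 ± 0.57), fell. Gdf15 and Hamp each lost the call in 7 of 24 alternatives, and without high-fat replicate 5 no hepatokine gene rose and 2 fell.

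With D-allulose 1 of the 22 acute phase genes fell against the high-fat diet (9 adjusted over the list alone; camera adjusted p = 3.21e-09; adjusted p = 0.478 with an estimated correlation). That gene was Steap4 (-1.32 ± 0.31), which did not pass without any single library of the 2 groups, such as high-fat replicate 3, 5, 7 or 12 or D-allulose replicate 1, 2, 5 or 7. The values of Orm2 (-1.94 ± 0.53), Orm1 (-1.38 ± 0.39) and Lcn2 (-1.67 ± 0.58) did not pass.

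Camera called further lists, most of them with few members past the gene test. On the high-fat diet these were, as lower, fatty acid and triglyceride synthesis (8 of 24 members fell, adjusted p = 5.95e-05), gluconeogenesis and glycogen (5 of 16 fell, 8.17e-06), bile acid synthesis and transport (3 of 21 fell and 1 rose, 0.00268), male-biased liver genes (5 of 14 fell, 0.00103), fatty acid oxidation and ketogenesis (0.00093) and nuclear oxidative phosphorylation (1.64e-06). As higher they were cytokines and inflammatory signalling (9 of 17 rose, 1.64e-06), neutrophils (3 of 4 rose, 0.00093), NRF2 and glutathione (5 of 22 rose and 1 fell, 0.0314), immediate early genes (4 of 17 rose, 0.000157), lymphocytes (3 of 14 rose, 0.0411) and cell cycle (2 of 24 rose, 5.71e-05). With an estimated correlation their adjusted p lay between 0.196 (as for gluconeogenesis) and 0.566 (lymphocytes). The NRF2 list lost its call without normal-diet replicate 1, 4 or 6 or high-fat replicate 12 (0.0577, 0.0524, 0.0526 and 0.196), and the lymphocyte list without normal-diet replicate 5 or 6 or high-fat replicate 5 or 12 (0.162, 0.169, 0.292 and 0.0779).

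With D-allulose against the high-fat diet the further called lists were interferon response (2.11e-06), immediate early genes (0.0111), cytokines and inflammatory signalling (0.0289) and cell cycle (0.0289) as lower. Cytosolic ribosomal proteins (1.24e-05), nuclear oxidative phosphorylation (4.36e-05), fatty acid oxidation and ketogenesis (0.0362) and lipoprotein and sterol efflux (0.0483) were called as higher. With an estimated correlation their adjusted p lay between 0.664 and 0.925. Without high-fat replicate 3, 5 or 12 or D-allulose replicate 2, 5 or 7, some of the lists of fatty acid oxidation, lipoprotein, cytokines, cell cycle and immediate early genes lost their calls, with adjusted p up to 0.732 for fatty acid oxidation without high-fat replicate 5. With erythritol they were interferon response (1.07e-05) and mitochondrially encoded transcripts (0.000489) as lower, and the urea cycle and amino acid catabolism (0.000316), cholangiocytes (0.000524) and antigen presentation (0.00121) as higher, each with adjusted p = 0.827 with an estimated correlation. Without high-fat replicate 5 the urea cycle list was at 0.201 and the mitochondrially encoded list at 0.973, without high-fat replicate 12 the urea cycle list was at 0.175, and without high-fat replicate 7 the antigen presentation and cholangiocyte lists were at 0.157 and 0.126. Lists not called on the high-fat diet were glycolysis, fructose and pentose phosphate (adjusted p = 0.214), lipoprotein and sterol efflux (0.0719), CAR and PXR drug metabolism (0.339), interferon response (0.919), erythroid cells (0.694), circadian clock (0.77), female-biased liver genes (0.519), mitochondrially encoded transcripts (0.496) and cytosolic ribosomal proteins (0.164). These adjusted p-values come from camera with Benjamini-Hochberg adjustment.

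Between the sweetened diets the further called lists were, as higher with D-allulose, urea cycle and amino acid catabolism (camera adjusted p = 1.36e-05), fatty acid oxidation and ketogenesis (0.000337), sinusoidal endothelium (0.00061), gluconeogenesis and glycogen (0.000809), cytosolic ribosomal proteins (0.000809), lipoprotein and sterol efflux (0.00564) and mitochondrially encoded transcripts (0.0116). As lower they were cell cycle (0.00507), unfolded protein and integrated stress response (0.00607), immediate early genes (0.0213), macrophages and Kupffer cells (0.0352) and acute phase (0.0445). With an estimated correlation their adjusted p lay between 0.674 and 0.726. The lists of lipoprotein and sterol efflux, cell cycle and mitochondrially encoded transcripts lost their calls without D-allulose replicate 7 (0.0865, 0.316 and 0.584). The macrophage list did so without D-allulose replicate 7 or erythritol replicate 2 or 7 (0.338, 0.47 and 0.136), and the stress response list without erythritol replicate 7 (0.371). The acute phase list did so without D-allulose replicate 2 or 5 or erythritol replicate 2 or 7 (0.093, 0.269, 0.0581 and 0.84), and immediate early genes without D-allulose replicate 5 or erythritol replicate 2 or 7 (0.0735, 0.0585 and 0.0929).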
